A study of Arabidopsis thaliana with 20 samples.

How the data were processed

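The series holds 20 samples of total RNA from wild-type Arabidopsis thaliana plants of the ecotype Columbia 0. Per the labels, 10 samples came from plants kept at a normal CO2 level and 10 from plants that had spent the last 96 h at a low CO2 level of 0.003% by volume. The labels number the samples 1 to 10 in each group. They do not say which numbers came from separate plants, separate RNA extracts or separate arrays.

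The values are the authors' deposited intensity values, 1 per probe and sample, on a linear scale. The scaling, background correction and array type behind them are not given in the sources used here. The values themselves show 3 features of that processing. Column totals lay between 3495 and 3797, values of exactly 0 made up 4.77% to 6.48% of a column, and 18 values in 12 columns, from 4 probes, sat at the same ceiling just under 100. A probe at the ceiling has only a lower bound there. Levels of different probes were compared only as signal, to rank or match probes by brightness, and not as amounts of transcript. No background measurement was used here, so how far a value lies above background is not known. The precision of a change is given by its standard error, which differed between probes.

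All 3439 probes entered the analysis. The platform annotation tied 692 probes to 1 gene and 870 to several genes, and 1877 were not listed in it. Of the 692, 690 matched a gene of the reference table (TAIR10.1), which supplied the AGI codes and symbols used as identities. The array's genome build is not given in the sources used here, so no coordinates are printed. No gene was named from a probe with several genes.

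Values of 0 were treated as missing and the others were put on the log2 scale with no pseudocount. Column medians on that scale ran from -1.59 to -0.77, a spread above the limit of 0.1 fixed for leaving the columns as deposited, so each column was centred on its median. Levels are therefore log2 signal relative to the column median, and a change is low CO2 minus normal CO2.

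The fits, the alternatives, 26 gene lists and the rule for naming genes were written down before the data were examined. That plan averaged repeat measurements only if columns whose deviations from the group mean clustered at r of at least 0.5 formed the same sets of numbers in both groups, and otherwise entered all 20 columns separately. The condition was not met: 2 pairs of normal CO2 columns and 1 pair of low CO2 columns reached 0.5. The fit reported here departs from the plan. Each of the 20 columns correlated best with its neighbour in number, so neighbouring numbers were averaged, giving 5 averaged pairs per group. Where 1 column of a pair held a 0, the other stood alone. This averaging had been listed beforehand as another way to treat repeats, and it was chosen from the correlations before any test was run. The result of the plan as written, with 20 separate columns, is printed beside it. The labels do not state that neighbouring numbers are repeat measurements.

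Probes with a value in at least 3 averaged pairs of each group were tested, which left 3277. The test was limma 3.58.1 (lmFit, then eBayes with a variance trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Gene lists with at least 4 tested genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. The code was tested on simulated data for this comparison with 3277 probes. It recovered 78 of 100 probes given a log2 change of size 1 and 91 of 100 given a change of size 2, with 6 calls among 3077 unchanged probes. The simulated values were independent normal draws with each probe's fitted SD. They held no missing values and no deviation shared between probes of a column. These figures therefore check the code and do not measure recovery or false calls in the real data.

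Named genes were the 10 with the largest rise and the 10 with the largest fall past the threshold, where that many existed, and for each list its 2 largest passing members or, where none passed, the member with the smallest p. All carbonic anhydrases and up to 4 photorespiration genes were to be named as well. The rule gave 16 genes. The second member of lists with 2 measured genes is given beside the first, outside this rule.

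The comparison was refitted under 22 alternatives: the replicate number as a block, 20 separate columns, 20 columns with neighbouring numbers as a random block, quantile normalization, no centring, cyclic loess, a pseudocount of 0.0403 (the 10th percentile of all values), zeros set to the lowest positive value of the column, removal of the dimmest 25% of probes, eBayes without a trend, robust eBayes, array weights, and removal of each of the 10 averaged pairs in turn. The random block was chosen after the data were seen. A stricter threshold of 0.01 was applied to the counts.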

Results

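Transcript levels were compared in wild-type Arabidopsis thaliana (Columbia 0) kept at a normal CO2 level and after 96 h at 0.003% CO2 by volume; CO2 is the carbon source of photosynthesis. The study belongs to work on how transcripts of nuclear genes for chloroplast proteins respond to environmental conditions. Each group held 10 columns of array intensities. Column totals were 3495 to 3749 in normal CO2 and 3604 to 3797 in low CO2. The 10 most intense probes took 10.6% to 21.2% of a column's total in normal CO2 and 11.8% to 19.3% in low CO2.

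The columns of a group were not equally distant from each other. In both groups every column deviated from its group mean most like its neighbour in number, 1 with 2, 3 with 4 and so on, in 20 of 20 columns. The correlation between neighbours, taken across probes, which are not independent replicates, was 0.39 to 0.87 in normal CO2 and 0.29 to 0.64 in low CO2. The highest correlation with any other column was 0.16 in normal CO2 and -0.03 in low CO2. Neighbouring columns were therefore averaged and counted once, so that n = 5 averaged pairs per group. Nothing in the labels says that these pairs came from separate plants, and p-values then measure only the spread between these samples, which may be technical.

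**Figure D1:**
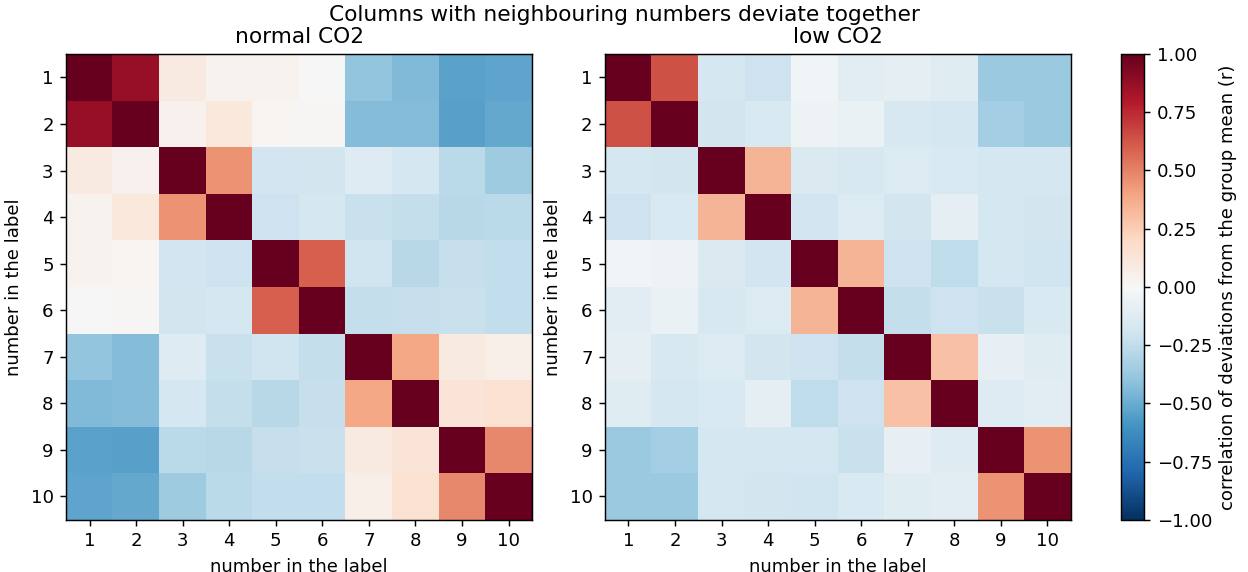
Correlation (r, colour scale) between the columns of a group in their deviations from the group mean, across 3105 probes in normal CO2 and 2982 in low CO2; both axes give the number in the label. Blocks of neighbouring numbers stand out along the diagonal, with r of at least 0.39 in normal CO2 and 0.29 in low CO2.

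The comparison asked which transcripts differed between the normal CO2 samples, marked 0d in their titles, and the low CO2 samples, marked 4d. Low CO2 and time changed together, and the design cannot tell their effects apart. The clearest change in a named gene was the fall of LHB1B2 (LHCB1.5, AT2G34420), which encodes a chlorophyll a/b-binding protein of the photosystem II antenna. Its log2 level was 3.99 ± 0.67 (SD, n = 5) in normal CO2 and 1.21 ± 0.37 (SD, n = 5) in low CO2, 6.86-fold lower, and all 5 low CO2 pairs lay below every normal CO2 pair. The limma fit gave a log2 change of -2.78 ± 0.29 (SE), adjusted p = 0.000361. The other LHCB1 genes have nearly the same sequence, and signal from them on this probe could not be told apart from that of LHB1B2. The probes of LHB1B2 and AT1G62250 belonged to a class of probe numbers, those leaving 1 when divided by 6, that held 24 of the 57 called falls and 17.4% of the tested probes. AT1G62250 fell 2.43-fold, from 3.70 ± 0.61 to 2.42 ± 0.24 (SD, n = 5 each), with limma's adjusted p = 0.0233, and 4 of its 5 low CO2 pairs lay below every normal CO2 pair. AT4G31470, a member of the plant family of cysteine-rich secretory proteins, fell 1.70-fold, from 2.38 ± 0.35 to 1.62 ± 0.19 (SD, n = 5 each), with limma's adjusted p = 0.0453, and all 5 low CO2 pairs lay below every normal CO2 pair.

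4 named genes rose, and in each of them all 5 low CO2 pairs lay above every normal CO2 pair. AT3G53580, which encodes diaminopimelate epimerase, an enzyme of lysine synthesis, was 1.92-fold higher, with a log2 change of 0.94 ± 0.23 (SE) and limma's adjusted p = 0.0453. AT5G17280 was 1.68-fold higher, at 1.39 ± 0.09 against 0.64 ± 0.24 (SD, n = 5 each), with limma's adjusted p = 0.0201. AT2G38570 was 1.66-fold higher, with a log2 change of 0.73 ± 0.16 (SE) and limma's adjusted p = 0.0301. AT3G04560 was 1.54-fold higher, with a log2 change of 0.62 ± 0.15 (SE) and limma's adjusted p = 0.0453.

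**Figure D2:**
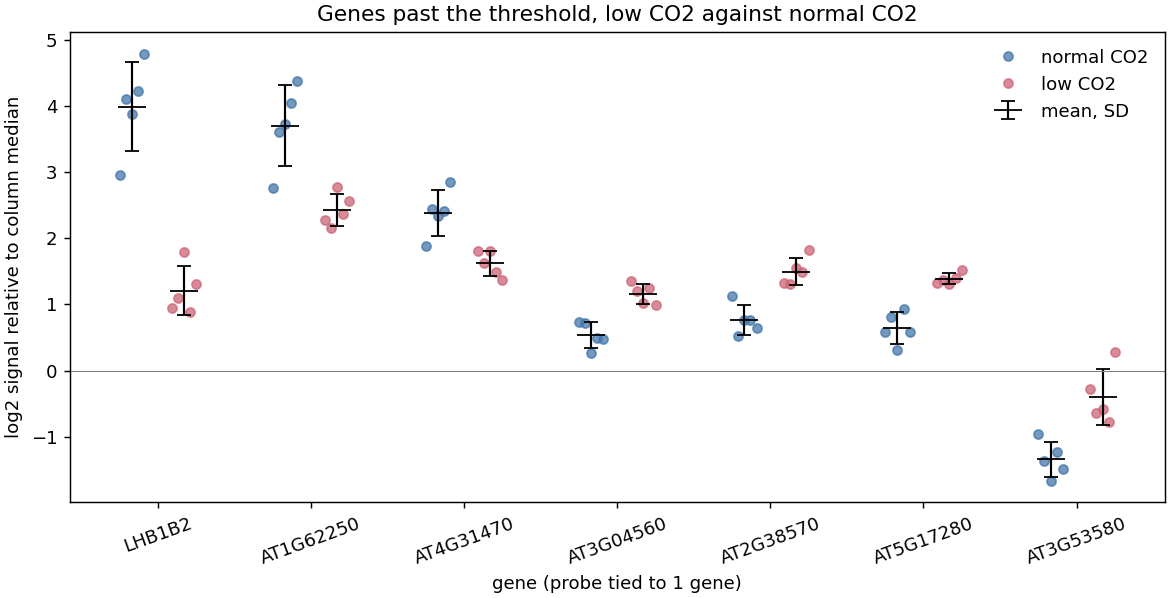
Log2 signal relative to the column median (y axis) of the 7 genes past the threshold (x axis) in normal CO2 and low CO2. Points are the 5 averaged pairs of columns of a group, bars the mean and SD. LHB1B2 stood at 2.96 to 4.79 in normal CO2 and 0.89 to 1.79 in low CO2, and each of the 4 genes on the right was higher in all 5 low CO2 pairs than in every normal CO2 pair.

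Over all probes, 69 of 3277 passed the threshold, 12 of them higher and 57 lower in low CO2. The rises had a median log2 change of 0.95, from 0.62 to 1.48, and 5 were at least 2-fold. The falls had a median of -1.19, the smallest being -0.68, and 39 were at least 2-fold and 7 at least 4-fold. Only 7 of the 69 probes were tied to 1 gene, while 11 were tied to several and 51 were not listed in the annotation. Among the unlisted probes, probe 2881 fell 8.01-fold and probe 2689 fell 6.94-fold, while probe 540 rose 2.80-fold and probe 2756 rose 1.79-fold. Falls outnumbered rises in this fit but not in the planned fit with 20 separate columns, which called 590 probes, 297 higher and 293 lower. That fit counts neighbouring columns as independent samples, though they deviated together, so its p-values overstate the evidence. With neighbouring columns as a random block, at a correlation of 0.749, 188 probes passed, 77 higher and 111 lower. This alternative was chosen after the data were seen.

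**Figure D3:**
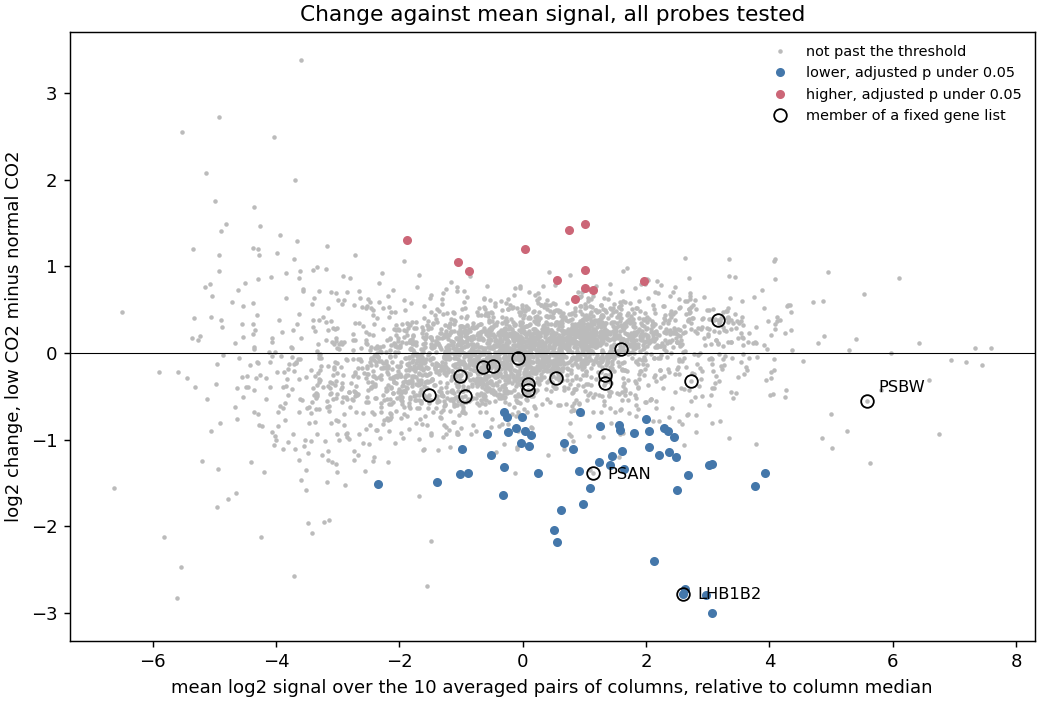
Log2 change, low CO2 minus normal CO2 (y axis), against the mean log2 signal relative to the column median (x axis) for the 3277 probes tested. Coloured points are the 12 higher and 57 lower probes past the threshold, and open circles are the 17 tested members of the gene lists, of which 15 lie below 0 and 1, LHB1B2, passed.

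Of the 417 genes in the 26 lists, 19 had a probe of their own and 17 could be tested, in 10 lists. The photosynthesis lists were measured by few genes. In the light-harvesting antenna list, LHB1B2 was the 1 measured member and fell. The photosystem I list was measured by PSAN, a subunit on the lumenal side of the complex, with a log2 change of -1.39 ± 0.38 (SE). Its levels were 1.84 ± 0.98 in normal CO2 and 0.45 ± 0.46 in low CO2 (SD, n = 5 each), and only 2 of the 5 low CO2 pairs lay below every normal CO2 pair. PSAN did not pass over all probes, with limma's adjusted p = 0.0835. As the 1 measured member of its list it has no further correction when adjusted over the list alone, and its unadjusted p in limma was 0.0026. It passed over all probes in 8 of the 22 alternatives. These included the fit without normal CO2 columns 1 and 2 (limma's adjusted p = 0.00234) and that with the replicate number as a block (0.0325). With 20 separate columns, which counts neighbouring columns as independent samples, limma's adjusted p was 0.002, and with the random block 0.00663. PSAN missed the threshold in the other 14, with a highest adjusted p in limma of 0.203, without normal CO2 columns 7 and 8.

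In photosystem II, neither of the 2 measured members passed. PSBW and PSBY, both small membrane subunits, had log2 changes of -0.55 ± 0.38 and -0.34 ± 0.22 (SE), and that of PSBY ran from -0.54 without normal CO2 columns 1 and 2 to -0.22 without normal CO2 columns 9 and 10. The Calvin cycle list had 2 measured members and none passed. The log2 change of SBPASE, which regenerates the CO2 acceptor, was -0.43 ± 0.19 (SE, limma's adjusted p = 0.267), and that of PRK, phosphoribulokinase, was -0.25 ± 0.20 (SE). SBPASE passed with 20 separate columns (limma's adjusted p = 0.0285), a fit that counts neighbouring columns as independent samples. With neighbouring columns as a random block, SBPASE did not pass (limma's adjusted p = 0.201). In tetrapyrrole and chlorophyll synthesis, with 2 measured members, neither CHLM (-0.50 ± 0.25, SE), the magnesium protoporphyrin methyltransferase, nor AT1G74470 (-0.32 ± 0.19, SE), geranylgeranyl reductase, passed. Photorespiration was measured by the plastid glycolate and glycerate transporter LrgB (PLGG1, AT1G32080), with a log2 change of -0.48 ± 0.23 (SE, limma's adjusted p = 0.312). It passed with 20 separate columns (limma's adjusted p = 0.0479) but not with the random block (0.355).

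Plastid ribosomal proteins were the 1 list with at least 4 tested genes. None of its 4 genes passed, 3 lay below 0, and the smallest p was that of AT4G01310, plastid ribosomal protein L5, at a log2 change of -0.36 ± 0.20 (SE), which ran from -0.46 without normal CO2 columns 1 and 2 to -0.24 without normal CO2 columns 9 and 10. The list's mean log2 change was -0.22 and its median -0.28, and it did not pass camera (p = 0.206, and p = 0.299 with an estimated correlation) or fry (p = 0.186). The mean turned to 0.0227 when zeros were set to the lowest positive value. In the remaining lists no member passed: AT5G17630, the plastid xylulose 5-phosphate translocator, had a log2 change of 0.38 ± 0.22 (SE), and FATB, a plastid acyl-ACP thioesterase, of -0.16 ± 0.21 (SE). Leaving out 1 averaged pair moved AT5G17630 between 0.19 (low CO2 columns 9 and 10) and 0.47 (normal CO2 columns 9 and 10), and FATB between -0.28 (normal CO2 columns 3 and 4) and -0.053 (normal CO2 columns 9 and 10). The antioxidant enzymes AT3G52960 (peroxiredoxin IIE) and NTRC had log2 changes of -0.15 ± 0.28 and -0.06 ± 0.21 (SE), and that of AT3G52960 ran from -0.41 without low CO2 columns 1 and 2 to -0.0084 without normal CO2 columns 5 and 6. Adjusted over the list alone, no member passed in the lists with more than 1 measured member.

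16 lists had no tested member on a probe of its own: photosynthetic electron transport and ATP synthase, carbonic anhydrases, chlorophyll breakdown and senescence, isoprenoid and carotenoid synthesis, plastid gene expression factors, starch synthesis, starch breakdown, the oxidative pentose phosphate pathway, plastid chaperones, plastid proteases, plastid protein import, nitrogen, sulfur and aromatic amino acid assimilation, sugar starvation and dark-induced genes, jasmonate synthesis, cytosolic and cytoskeletal reference genes, and root and seed marker genes. These groups are not analysed here.

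LHB1B2 passed in all 22 alternatives and without each of the 10 averaged pairs, with a highest adjusted p in limma of 0.00463. The other 6 called genes kept their direction in all 22, with log2 changes of -1.52 to -1.11 for AT1G62250, -0.89 to -0.65 for AT4G31470, 0.77 to 1.04 for AT3G53580, 0.66 to 0.82 for AT5G17280, 0.64 to 0.82 for AT2G38570 and 0.55 to 0.67 for AT3G04560, but each missed the threshold in some of them. AT5G17280 missed the threshold without normal CO2 columns 5 and 6 (limma's adjusted p = 0.069), without normal CO2 columns 9 and 10 (0.0529) and without low CO2 columns 3 and 4 (0.0536). AT1G62250, AT4G31470, AT3G53580, AT2G38570 and AT3G04560 each missed it without normal CO2 columns 3 and 4, 5 and 6, 7 and 8, or 9 and 10, and without low CO2 columns 3 and 4 or 9 and 10. AT3G53580 and AT3G04560 also missed it without low CO2 columns 1 and 2. Without low CO2 columns 5 and 6 all of these but AT1G62250 missed it, and without columns 7 and 8 all but AT3G53580. The highest adjusted p in limma over these left-out pairs was 0.0721 for AT1G62250, 0.123 for AT4G31470, 0.138 for AT3G53580, 0.0841 for AT2G38570 and 0.14 for AT3G04560. Among the other settings, eBayes without a trend ended the calls of these same 5 genes and no centring those of AT5G17280, AT3G53580, AT2G38570 and AT3G04560. AT3G53580 also missed the threshold with the pseudocount, the floor for zeros and the random block, AT4G31470 with the pseudocount, the floor and the replicate block, AT1G62250 with the floor, and AT3G04560 with quantile normalization and cyclic loess. The highest adjusted p in limma over all 22 alternatives was 0.182, for AT3G04560 with no centring. The count of 69 rose to 124 without normal CO2 columns 1 and 2. It fell to 32, 25, 26 and 26 without normal CO2 columns 3 and 4, 5 and 6, 7 and 8, and 9 and 10. Without low CO2 columns 3 and 4 it was 25, and without low CO2 columns 9 and 10 it was 33.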

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

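In 2 of the 32 groups of 5 averaged pairs examined for the named genes, 1 pair lay far from the others; chance alone gives about 1.6 such groups. The log2 level of AT5G17630, the xylulose 5-phosphate translocator, was 4.09 in low CO2 columns 9 and 10, against a group mean of 3.35 ± 0.41 (SD, n = 5). Without this pair its log2 change between the groups was 0.19 in place of 0.38. The log2 level of AT3G52960, peroxiredoxin IIE, was 0.47 in low CO2 columns 1 and 2, against a group mean of -0.56 ± 0.59 (SD, n = 5). Without this pair its log2 change was -0.41 in place of -0.15, while without normal CO2 columns 5 and 6 it was -0.0084. Neither gene passed the test between the groups, with or without the pair.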

How the results depend on the processing

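The fit with neighbouring columns as a random block was chosen after the data were seen; the other settings were planned. The cause of the following moves was not tested unless stated. Of 69 probes past the threshold (12 higher, 57 lower), a threshold of 0.01 left 20 (2 higher, 18 lower), by its construction. Entering 20 separate columns, which counts neighbouring columns as independent samples, gave 590 (297 higher, 293 lower) and included all 69. The random block, at a correlation of 0.749, gave 188 (77 higher, 111 lower) and shared 64. Setting zeros to the lowest positive value gave 30 (6 higher, 24 lower), and eBayes without a trend gave 34 (5 higher, 29 lower). Quantile normalization gave 103, of which 89 were lower, cyclic loess 100, of which 87 were lower, and no centring 77, of which 7 were higher. Leaving out 1 averaged pair at a time gave 25 to 124 probes, 2 to 22 higher and 22 to 103 lower; the fits without low CO2 columns 1 and 2 and without low CO2 columns 3 and 4 gave 22 and 2 higher. The pseudocount (55), the dim filter (79), robust eBayes (76) and array weights (81) stayed within 1.5 times the count.

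Whether the numbers pair the samples stayed open. Averaged pairs of the same number correlated at -0.07 to 0.39 across the groups in their deviations, above 0.1 in 3 of 5, and 3 of 5 correlated best with their own number. Single columns of the same number correlated at 0.11 to 0.40 for numbers 1 to 8, and at -0.05 and -0.08 for numbers 9 and 10. Part of the samples thus shared a deviation by number, which the unblocked fit left out. With the replicate number as a block, 89 probes passed (24 higher, 65 lower), 62 of them shared with the unblocked fit.

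The mean change of the plastid ribosomal proteins, -0.22, reversed to 0.0227 when zeros were set to the lowest positive value (camera p = 0.356) and stayed below 0 in the other settings run. Camera has no setting for robust eBayes or a random block, so these were not run for the list. Over the 16 named genes, 280 refits kept the side of the threshold, 61 lost a call, 10 gained one and none reversed. With 5 averaged pairs per group, the median standard error was 0.23 on the log2 scale.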

Other observations

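Only the share of falls after cyclic loess and the count over splits of the samples were tested as written beforehand; the left-out pairs for the share of falls, both tests of the photosynthesis genes and both tests of the probe numbers were chosen after the values were seen.

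Of the 651 tested genes with a probe of their own, 17 had an unadjusted p under 0.005 in limma, where 3.26 are expected by chance. The 7 called genes are among them, and the other 10, of which 5 were higher and 5 lower, missed the adjusted threshold. PSAN is one of the 10, and the others given here were named after their values were seen. DI21, known as a drought-induced gene, had a log2 change of -0.96 ± 0.28 (SE, adjusted p in limma 0.101). The plastid protein CUTA had one of -0.91 ± 0.24 (SE, adjusted p in limma 0.0671). The value closest to the threshold was that of AT5G24690, at 0.84 ± 0.21 (SE, adjusted p in limma 0.0507).

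Of the called probes, 82.6% were lower in low CO2, against 48.7% of all tested probes. The number of calls was not reached by reshuffling the averaged pairs. Of 100 splits of the 10 into 5 and 5, drawn from 126, only 1, the real one, gave 69 calls, and the highest other gave 1. Splits that mix the groups hold the group difference within each part, so few calls are expected from them. If the pairs are technical repeats, a chance difference between the plants or RNA behind the groups cannot be excluded this way. The change did depend on brightness, with a median log2 change of -0.23 in the dimmest 10% of probes and 0.13 in the brightest 10%, but 87% of calls were still lower after cyclic loess. A single pair out of place would not account for the share either, since its lowest value without any one pair was 75.8%. The share does depend on how repeats are treated: with 20 separate columns it was 49.7% over all calls, made up of 85.7% among the 84 calls of at least 2-fold and 43.7% among the 506 smaller ones. That fit counts neighbouring columns as independent samples, and with the random block the share was 59.0%. With averaged pairs, falls outnumbered rises at both sizes, at 39 to 5 among calls of at least 2-fold and 18 to 7 among smaller ones, and why stays open.

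A hypothesis formed from the data is that photosynthesis and chlorophyll genes were lower as a group. All 8 measured genes of the photosystem, antenna, Calvin cycle and chlorophyll synthesis lists had changes below 0, also under cyclic loess, quantile normalization and no centring, but so had 7 of the other 9 tested list genes, whose median was -0.16. Random lists matched on mean level had medians centred on 0.12 against -0.46 for the 8, which stayed at -0.44 after cyclic loess, below the lowest 2.5% (-0.27) of 10000 matched random lists, and this argues against brightness as the whole cause. Without LHB1B2 the other 7 were all below 0 with a median of -0.43 (2.5% limit -0.25). A median hardly moves when its most extreme member is dropped, so the small move could not test that probe as the cause. The 7 still lay below the limit for matched lists, though they were chosen with their values known. These lists were joined after their values had been seen. Camera gave p = 2.7e-05 at the preset correlation but p = 0.0716 with an estimated correlation (correlation 0.485). A deviation shared by a few arrays or plants may therefore still account for the shift. The CO2 level, which the design names, and time, which differs with it, also stay open.

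Of the 57 called falls, 24 (42.1%) had a number that leaves 1 when divided by 6, a class holding 17.4% of the tested probes, where the two-sided Fisher's exact test gave p = 9.0e-06, and a permutation test for the fullest of the 6 classes p = 0.0036. The divisor was picked after other groupings of the numbers had been looked at, which neither p covers, so this is only a hypothesis. Fisher's exact test also counts probes as independent and takes no account of brightness. The class had the highest median log2 level of the 6, at 0.32, and 16 of the 57 falls lay in the brightest 10% of probes. The class holds the probes of LHB1B2, AT1G62250 and PSAN, the unlisted probes 2881 and 2689, and that of AT5G17280, a called rise; the unlisted probes 12 and 24 numbers after that of LHB1B2 had log2 changes of -2.73 and -2.79, against its -2.78, while the probes of the class 6 and 18 numbers after it, at -0.44 and -0.11, did not pass the test. Such gaps were not found throughout the class. The unlisted probe 3211, with a log2 change of -2.18, and the probe 6 numbers before it were both called falls. A longer run of called falls with no gap lay elsewhere in the class. A shift of the whole class is argued against by its median log2 change of -0.057 over 570 probes (SD 0.57). This lay far from the median of -1.32 of its falls. A local defect of the array or the print cannot be told apart from the placing of related genes in one class, for LHB1B2 and the other falls there, since the layout of the array was not used here; the 34 probes next in number within the class had a median of -0.28 (SD 0.48).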
